A study of Mus musculus with 8 samples.

How the data were processed

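RNA from the striatum of 8 adult male mice was measured, 4 wildtype and 4 heterozygous for a gene trap in Brd2, per the labels. The mice came from matings of heterozygotes after repeated backcrossing to C57Bl/6J and were genotyped by PCR across the trap junction, per the labels' protocols. Per the labels' protocols, the authors amplified the RNA and labelled that of each mouse with Cy3 or Cy5, and the series' design text states that mice of 1 genotype shared an array. Replicates 1 and 3 of each genotype carried Cy3 and replicates 2 and 4 carried Cy5, per the labels. The samples are separate mice, so the p-values measure the spread between mice together with that between arrays.

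The scanner files hold the raw spot and local background intensity of each channel, per the file headers, as read by Agilent Feature Extraction 11.0.1.1. They also hold the deposited processed intensity of each channel, which the scanner software subtracted for background, detrended and dye-normalized, per the file headers. The value table that the authors deposited holds a linear ratio, the median spot signal minus the median local background of the sample's channel, divided by the median of the column. This was found by setting each column against the scanner values of the same sample, since no header or label states it, and 100% of the values were equal within floating-point rounding. Each column's median is 1, with no centring across samples, and spots with a signal under about 2 times the background are empty, which left between 10844 and 14151 empty cells in the Cy5 columns and 8 to 42 in the Cy3 columns. Log2 values were computed here from the deposited intensities. Any further step of the authors is not given in the sources used here.

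Each sample's own channel gave its value. Background was corrected with normexp (offset 50) on the mean spot signal and the median local background, followed by loess within arrays and Aquantile between arrays, with limma 3.58.1 in R 4.3.3. Background readings with an outlier flag were replaced by the channel's median background. Control spots and spots with an outlier flag were left out, and spots of the same probe were averaged. A probe was kept where it was well above background in at least 4 of the 8 samples, and each gene was read by its probe with the highest mean. Of 17426 genes with such a probe, 15018 had a value in all 8 samples and were tested, and 2408 were left out for outlier spots. Of the genes tested, 13075 had a symbol and 1943 were transcripts without one.

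Of 39429 probes, 27234 were named by matching the accession in the file to a RefSeq table of assembly GRCm38.p6, used for names only, 5949 kept the file's gene name, and 6246 had no gene name. Coordinates are those of the file, on mm9, per the file headers. A genome of that build was not used here. Of the 34 named genes with several kept probes, 13 had probes that differed in sign.

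The genotypes were compared with limma (lmFit and eBayes) with dye as a covariate and the array as a random block (duplicateCorrelation), and p-values were adjusted by Benjamini-Hochberg at 0.05. The dye covariate follows the series' design text, in which samples of the same dye were compared and the results averaged. Brd2 was also tested with two-sided exact permutation tests over samples and over arrays. The 23 gene lists and 17 cell type lists were tested with camera (preset correlation of 0.01), with camera using an estimated correlation and with fry, and adjusted within each kind. The gene lists cover synapses and channels, transcription and growth, metabolism and protein turnover, inflammation, and the neighbours of Brd2. The cell type lists cover striatal, cortical and other neurons, glia, vessels, meninges, choroid plexus, ependyma, blood and heart. Genes within 5 Mb of Brd2 were compared with all others by a two-sided Fisher's exact test.

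Named genes followed a rule set, like the lists, the tests and most alternatives, before the data were examined. The rule takes Brd2, the 10 genes per direction with the largest change among those past the test, up to 4 members of each gene list and 3 of each cell type list by unadjusted p, and the most abundant marker. Where fewer than 10 genes passed, as here, it fills up with the lowest unadjusted p among genes at least 1.5-fold apart whose groups do not overlap. It gave 167 genes, of which a portion is named in the text, picked with their values in view, and none passed. Tbr1 and Nppa were chosen after their values were seen. A gene's predicted name or clone name was left out of the ranked genes. The values of 3 list members are not reported here.

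The depth of each sample is the signal of its spots over background, 3.72 to 10.6 at the median, and 41.6% to 63.1% of probes were well above background. Every Cy5 sample had a lower signal over background than any Cy3 sample. The fits were tested on simulated data with the spread between arrays found here. In 1 simulation without any change, limma called 1 gene among 15018 and 942 at an unadjusted p under 0.05, while without the array block it called 185. Chance at that p would give 751, so the unadjusted p-values may be too small.

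The alternatives replaced the normalization (processed signals minus the percentile 75 of each channel, quantile normalization, the deposited table), the background correction (none, offset 16), the filter on dim probes (none, all 8 samples), the probe per gene (mean of probes, each probe), the array block (none, separate-channel model, channels averaged), the covariate (no dye term, replicate block), the moderation (trend and robust) and the samples (each dye alone, without each sample, without each array). Alternatives chosen after seeing the data were the removal of each array's spatial trend, the keeping of outlier spots, and the fit without wildtype replicates 1 and 4. Figures were drawn with matplotlib 3.10.9.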

Results

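The series asks how a lowered dose of Brd2 alters gene expression in the male mouse striatum, and its title names synaptic transmission as the process affected. Brd2 encodes a BET (bromodomain and extra-terminal) protein, a reader of acetylated histones that takes part in transcription. Total RNA from the striatum of 4 adult wildtype males and 4 males genotyped as heterozygous for a gene trap in Brd2 was measured on 4 Agilent mouse gene expression arrays. Each array held 2 mice of the same genotype, 1 labelled with Cy3 and 1 with Cy5, so that each genotype came from 2 arrays. All 4 arrays lay on 1 slide and were scanned once, with the wildtype arrays at positions 4 and 3 and the heterozygous arrays at positions 2 and 1. Of 39429 probes, between 16398 (heterozygous replicate 3) and 24867 (heterozygous replicate 2) stood well above background in a sample. The next lowest sample had 21010. The median spot was between 3.72 times (heterozygous replicate 4) and 10.6 times (wildtype replicate 1) as bright as its local background, and no spot was saturated. This range followed the dye, with 6.57 to 10.6 in the Cy3 samples and 3.72 to 5.24 in the Cy5 samples. The number of arrays limits the precision of every difference between the genotypes. The correlation across probes was 0.989 to 0.990 between the mice on 1 array and 0.950 to 0.972 between mice on different arrays, across genes that are not independent replicates.

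The labels name the tissue in 2 ways, as striatum in the tissue and protocol fields and as left atrium of the heart in the free description. Of 25 genes of striatal projection neurons on the array, 24 were well above background in all 8 samples. Ppp1r1b, the dopamine-regulated phosphatase inhibitor of striatal projection neurons, read 16.30 ± 0.50 log2 units in wildtype samples (SD, n = 4), Penk, the enkephalin precursor of the indirect pathway, 15.66 ± 0.56 and Tac1, the substance P precursor of the direct pathway, 13.78 ± 0.58. Of 30 genes of atrial heart muscle, 7 were well above background in all 8 samples and 12 in none. Nppa, the atrial natriuretic peptide and a gene chosen after its values were seen, lay between 6.98 and 8.14 log2 units.

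The targeted gene was examined first, because a loss of 1 working copy should show in its own transcript where a probe reads the part that is lost. Brd2 was not lower in the samples labelled heterozygous. The brighter of its 2 probes, A_55_P1958678 (chromosome 17, 34248982 to 34249041, mm9), read 11.46 ± 0.65 log2 units in the wildtype samples (SD, n = 4) and 11.75 ± 0.06 in those labelled heterozygous (SD, n = 4). The difference of 0.29 (SE 0.36, 95% interval −0.52 to 1.09) was smaller than the spread between wildtype arrays. The interval counts both mice of an array toward its degrees of freedom and may be too narrow, since genotype varied only between arrays. A two-sided exact permutation over samples, which treats the mice of an array as independent, gave p = 0.429. The wildtype values were 11.05 and 10.76 on 1 array and 12.01 and 12.02 on the other, whereas the values labelled heterozygous lay between 11.67 and 11.82.

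The second Brd2 probe, A_55_P1953545 (chromosome 17, 34255967 to 34256026, mm9), was dimmer and read higher in the samples labelled heterozygous. It was well above background in 7 of the 8 samples. Its level was 7.13 ± 0.26 in wildtype samples and 8.01 ± 0.18 in those labelled heterozygous (SD, n = 4 each), a difference of 0.88 (SE 0.28). The 4 values of each group did not overlap (two-sided exact permutation p = 0.0286, the smallest that 4 samples against 4 can give). With whole arrays as the units, the permutation p was 0.333, the smallest that 2 arrays against 2 can give. The place of either probe against the trap is not given in the labels, so the probes do not check the genotypes. The sign of the brighter probe turned with the scanner's own processed signals (−0.042), without the array of wildtype replicates 1 and 2 (−0.27) and with the spatial trend of each array removed (−0.40). Every direction below is drawn from the genotype labels, which the Brd2 signal could not check.

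**Figure D1:**
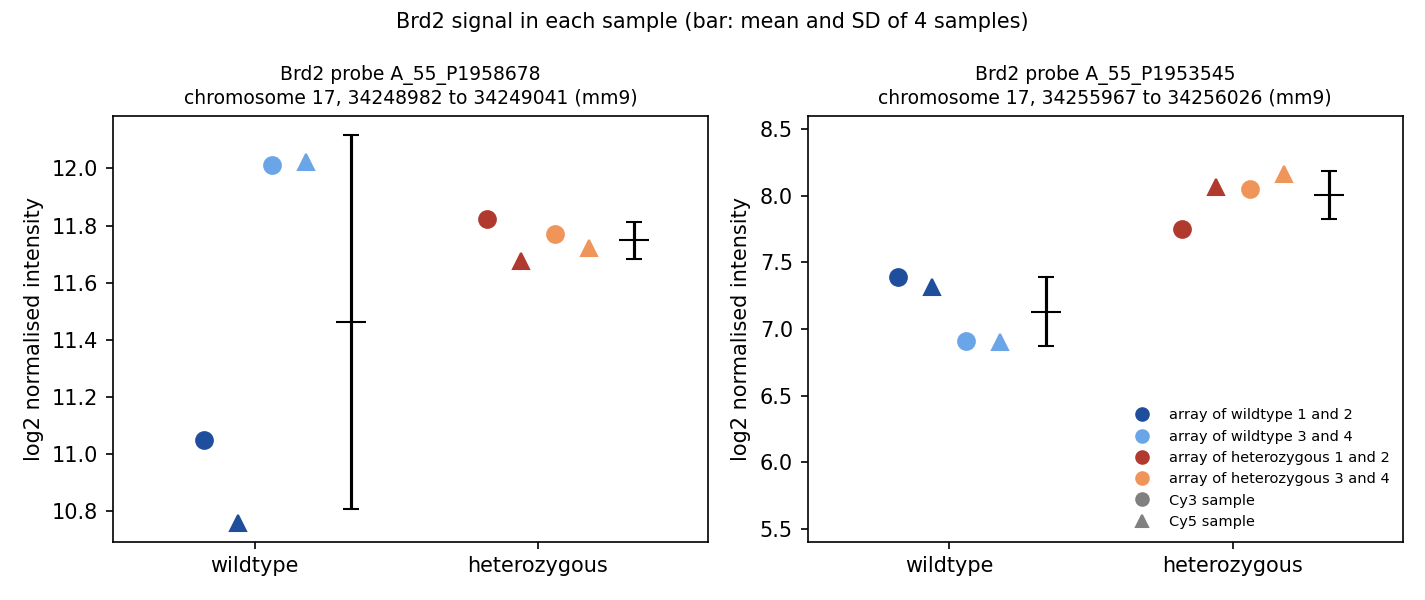
Normalised log2 intensity of the 2 Brd2 probes in each of the 8 samples, by genotype label, with the mean and SD of 4 samples as bars, colours for arrays and symbols for dyes. The brighter probe averages 11.46 in wildtype and 11.75 in heterozygous samples, and the dimmer probe 7.13 and 8.01.

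The comparison of the genotypes over all genes asks which transcripts differ in the striatum of Brd2 heterozygous males. No gene passed the test, and the samples labelled heterozygous are described below by the genes that ranked first. Olfr1349, an olfactory receptor gene, had the largest difference of these, with 9.76 ± 0.40 log2 units in wildtype samples and 6.94 ± 0.11 in those labelled heterozygous (SD, n = 4 each). Impdh2, the inosine monophosphate dehydrogenase of guanine nucleotide synthesis, had the largest difference upward, 8.47 ± 0.35 against 10.36 ± 0.42, a rank that held for 1 of its probes: without wildtype replicate 1, where a brighter probe reads the gene, it stood at 0.84. Syt10, a synaptotagmin, read 11.50 ± 0.33 in wildtype and 8.83 ± 0.67 in the samples labelled heterozygous.

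Limma called 0 of 15018 genes at an adjusted p of 0.05, and the lowest adjusted p was 0.448. At an unadjusted p under 0.05 there were 1178 genes (7.84%), of which 555 were higher and 623 lower in the samples labelled heterozygous. Of these, 1121 were also at least 1.5-fold apart, 532 higher and 589 lower. Data simulated once with this array correlation and no change gave 942 and 744. For the unadjusted p alone, 751 genes would be expected by chance, so the fit's unadjusted p-values may be too small. With the scanner's processed signals in place of the intensities normalised here, 24.9% of the genes at an unadjusted p under 0.05 and at least 1.5-fold were higher, against 47.5%. Of the 82 genes followed through the alternatives, 44 turned or moved by over 1.5 times with these signals, 41 of them toward 0. The values of the groups did not overlap in 2545 genes (16.9%), where chance gives 2.86% for independent samples, and the 2 mice of an array were not independent, with an array correlation of 0.813. Limma without the array block called 443 genes, its separate-channel model 0 and the averages of both channels of an array 0. In data simulated with this spread between arrays, the same fit recovered 0% of genes changed 1.5-fold, 10% of those changed 2-fold, 54% at 4-fold and 88% at 8-fold among 15018 genes.

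The genes ranked first in each direction, none past the test, are each given as the log2 difference of the samples labelled heterozygous from wildtype. Upward, the probe of Impdh2 (chromosome 9, 108467842 to 108467901, mm9) stood at 1.90 (SE 0.32), followed by Eif3f, a subunit of translation initiation factor 3, at 1.73 (SE 0.29). Kat7, a histone acetyltransferase (chromosome 11, 95135574 to 95135633, mm9), had 10.61 ± 0.07 in wildtype and 11.90 ± 0.08 in the samples labelled heterozygous, a difference of 1.29 (SE 0.23). Rpp21, a subunit of ribonuclease P, stood at 1.74, where its other probe read 0.076, Acot1, an acyl-CoA thioesterase, at 1.72, and Lyrm2 at 1.52. Plekhm1 stood at 1.36, Phlpp2, a phosphatase of Akt, at 1.21, Ackr3, an atypical chemokine receptor, at 1.15, and Pelp1 at 1.13. Lyrm2 had 1 wildtype sample, replicate 1 at 8.57, below the other 3 at 8.99 to 9.05.

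Downward, the probe of Olfr1349 (A_55_P2118259, chromosome 7, 6467259 to 6467318, mm9) stood at −2.83 (SE 0.37) and that of Syt10 (chromosome 15, 89612967 to 89613026, mm9) at −2.67 (SE 0.47). Puf60, a splicing factor, had 13.09 ± 0.09 in wildtype and 11.70 ± 0.12 in the samples labelled heterozygous, a difference of −1.39 (SE 0.22). Rplp0, the acidic stalk protein of the ribosome, had 14.08 ± 0.18 and 12.71 ± 0.08, a difference of −1.37 (SE 0.23). Other probes read Rplp0 at −0.15 without the array of heterozygous replicates 3 and 4, and at −0.75 with outlier spots kept. Dcun1d5 stood at −1.45, Cdc16, a subunit of the anaphase-promoting complex, at −1.39, and Polr1e, a subunit of RNA polymerase I, at −1.27. Cblb, a ubiquitin ligase, stood at −1.15 (−0.63 for its other probe), Sugt1 at −1.05 and Krit1 at −1.03 (−0.18 for its other probe). A second probe of Polr1e read 0.026, and with the scanner's processed signals Kat7 stood at 0.07, Phlpp2 at 0.46, Rpp21 at 0.77, Impdh2 at 1.20 and Olfr1349 at −4.64. Olfr1349, Cblb and Polr1e were well above background in 3 of the 4 samples labelled heterozygous. The call of Olfr1349 depended on single samples and settings, with an adjusted p of 0.0291 in limma without wildtype replicate 4 (−2.98) and a range of 0.0118 to 0.853 over 30 alternatives.

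**Figure D2:**
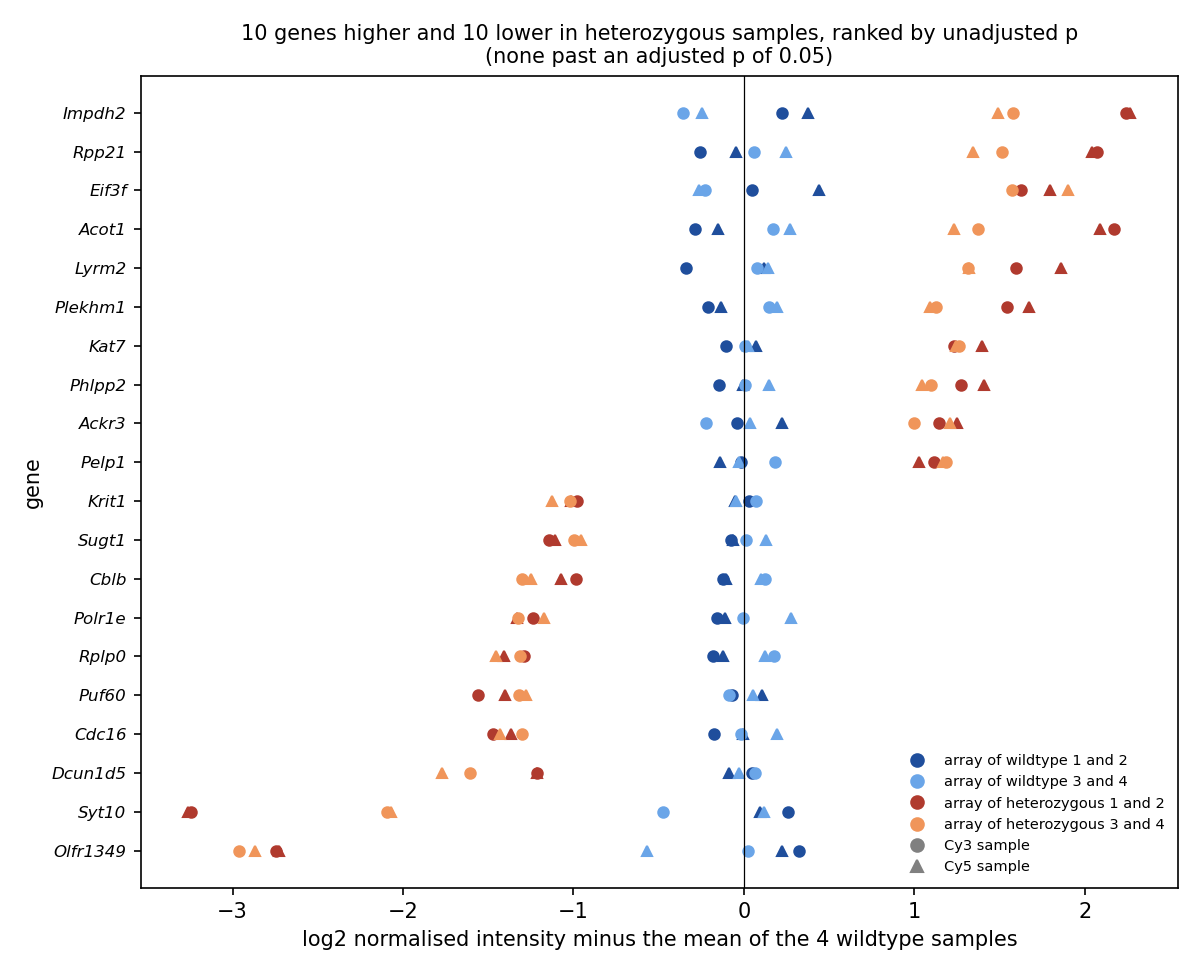
Log2 intensity of the 20 genes ranked first, 10 higher and 10 lower in the samples labelled heterozygous, as the deviation of each of the 8 samples from the mean of the 4 wildtype samples, with colours for arrays and symbols for dyes. Olfr1349 and Syt10 lie lowest, at mean differences of −2.83 and −2.67, and no gene passed an adjusted p of 0.05.

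The gene lists ask whether synaptic transmission, BET-dependent transcription or another process moved as a group. Cholesterol synthesis came nearest, with 16 of 21 genes lower in the samples labelled heterozygous and a median of −0.33. Relative to the mean of all 8 samples, the list's median lay between 0.10 and 0.34 in the 4 wildtype samples. It lay between −0.23 and −0.13 in the 4 labelled heterozygous. These signs add no test to the list's difference, since the list was picked for that difference and the values are centred on all samples. The mice of an array were also not independent, so the 4 values of a group do not count as 4 separate agreements. The lists of synaptic transmission were near 0, with medians from −0.12 to 0.11. None of the 23 lists passed camera at an adjusted p of 0.05.

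In cholesterol synthesis, Sqle, the squalene epoxidase, read 11.08 ± 0.40 in wildtype and 9.71 ± 0.24 in the samples labelled heterozygous, and Acat2 9.28 ± 0.14 and 8.28 ± 0.15 (SD, n = 4 each). The list had an adjusted p of 0.0673 in camera with the preset correlation, and p = 0.210 in camera with an estimated correlation of its genes. It passed an adjusted p of 0.05 in several alternatives, among them the fit without the dim-probe filter (−0.31) and the one with the spatial trend removed (−0.09). In the latter fit most of the planned fit's median of −0.33 was gone. Over 31 alternatives the list's adjusted p in camera ran from 0.0036 to 0.239.

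Of the lists of transmitters, the dopaminergic synapse had a median of 0.11, with 27 of 40 genes higher (adjusted p = 0.337). Within it Cacna1d, an L-type calcium channel subunit, stood at −0.81 and Fos at 1.05. The serotonergic synapse had 0.093 (10 of 15 higher, adjusted p = 0.480), with Dusp1, a phosphatase of MAP kinases, at 1.54 and Ptgs1 at −0.64. The endocannabinoid and opioid list had 0.024 (9 of 17 higher, adjusted p = 0.337), with Mgll, the lipase of 2-arachidonoylglycerol, at 0.92 and Pdyn, the dynorphin precursor, at 0.78, the latter from a probe well above background in 1 of 4 wildtype samples and 3 of 4 labelled heterozygous. The GABAergic synapse had 0.032 (16 of 29 higher, adjusted p = 0.667). In it Gabarap stood at 0.51 and Slc32a1, the vesicular GABA transporter, at 0.93. The glutamatergic synapse had −0.072 (22 of 40 lower, adjusted p = 0.902), with Cacng2, an AMPA receptor auxiliary subunit, at 1.30 and Gria1 at 0.46. The cholinergic synapse had −0.062 (12 of 21 lower, adjusted p = 0.846), with Chat, which makes acetylcholine, at 1.22 and Pik3r1 at −1.03. The synaptic vesicle cycle had −0.12 (23 of 40 lower, adjusted p = 0.846), with Atp6v1e1, a proton pump subunit, at 1.06. Neuropeptides and receptors had −0.11 (20 of 34 lower, adjusted p = 0.902), with Trh at 1.13 and Nmb at −0.77, where another Nmb probe read 0.55. Potassium channels had −0.076 (17 of 32 lower, adjusted p = 0.902), with Kcnip2 at 1.40, and sodium and calcium channels −0.053 (13 of 22 lower, adjusted p = 0.875), with Scn3a at 1.41. Without wildtype replicate 3 a brighter probe reads Scn3a, at 0.26. The signs of the GABAergic, serotonergic, endocannabinoid and neuropeptide medians and of Gabarap turned under at least 1 of the other scalings. The medians of the same 4 lists and of the cholinergic list turned without 1 sample or another, and that of the synaptic vesicle cycle was −0.00056 without wildtype replicate 1. With the processed signals, Mgll stood at 0.02, Atp6v1e1 at 0.04, Gria1 at 0.14, Slc32a1 at 0.19, Scn3a at 0.33, Chat at 0.46 and Kcnip2 at 0.64. Cacna1d was well above background in 3 of the 4 samples labelled heterozygous.

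Of the lists of transcription and growth, that of BET proteins and elongation factors had a median of −0.0086, with 20 of 36 genes lower (adjusted p = 0.922). Of the 36, 7 were at an unadjusted p under 0.05, where 7.84% of all genes tested were. Fry in either direction, which does not set a list against other genes, gave this list an adjusted p of 0.0024. That p may be too small, since fry counts both mice of an array toward its degrees of freedom. Hexim1, the inhibitor of the elongation factor P-TEFb, stood at 1.35 and Aff4, a scaffold of the super elongation complex, at −1.40. E2F and cell cycle genes had −0.085 (28 of 39 lower, adjusted p = 0.493), with Rbl2 at −0.83 and E2f7 at 1.68. E2f7 read 11.45 and 11.48 on the array of heterozygous replicates 1 and 2 but 8.68 and 8.77 on the other. Immediate early genes had 0.21 (17 of 28 higher, adjusted p = 0.337), with Nr4a1 at 1.62 and Nr4a2 at −2.42 (−1.25 for its other probe). The circadian clock list had 0.20 (14 of 22 higher, adjusted p = 0.337), with Dbp at 0.49. Histones had 0.13 (10 of 15 higher, adjusted p = 0.558), with H2aj at 0.59 (0.27 for its other probe, 0.20 with the processed signals). The sign of the BET median and of Dbp turned under another scaling, and the BET median also without wildtype replicate 1 (0.011).

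Of the lists of metabolism and protein turnover, cytosolic ribosomal proteins had a median of −0.22, with 34 of 53 genes lower (adjusted p = 0.337). Rpl27 stood at −0.93, where its other probe read 0.20, and Rpl29 at 0.97. Oxidative phosphorylation had −0.091 (23 of 40 lower, adjusted p = 0.932) and held genes that went both ways, with Ndufa8 at 1.21, Atp5k at 1.31, Ndufa6 at 1.15 and Sdhb at −0.95. Without heterozygous replicate 4 a brighter probe reads Sdhb, at 0.076, and without the array of wildtype replicates 1 and 2 a brighter probe reads Atp5k, at −0.13. The proteasome had −0.046 (14 of 21 lower, adjusted p = 0.989), with Psmb2 at 1.08, and the heat shock list 0.029 (15 of 27 higher, adjusted p = 0.694), with Hspe1 at −0.59. Another probe read Hspe1 at 0.15 with outlier spots kept, and at −0.22 without the array of wildtype replicates 1 and 2. Interferon response genes had 0.083 (16 of 25 higher, adjusted p = 0.337), with Irgm1 at 0.90 (0.26 for its other probe). The NF-kB list had 0.099 (13 of 16 higher, adjusted p = 0.337), with Traf2 at 0.72 and −0.14 for its other probe. The neighbours of Brd2 in the major histocompatibility region had 0.017 (20 of 38 higher, adjusted p = 0.480), with Col11a2 at 0.95 and Psmb9, an immunoproteasome subunit, at 0.86. The medians of the heat shock list and of the Brd2 neighbours turned under another scaling and without 1 sample or another (−0.034 without heterozygous replicate 4 and −0.017 without wildtype replicate 1). With the processed signals Ndufa6 stood at 0.21, Rpl29 at 0.39, Psmb2 at 0.55 and Traf2 at 0.30. Irgm1 was well above background in 3 of 4 wildtype samples, and Col11a2 in 3 of 4 of each group.

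Adjusted over the list alone, 6 members passed in the 23 lists, 4 in oxidative phosphorylation, 1 in ribosomal proteins and 1 in the serotonergic synapse, against 0 over all genes tested. When 1 sample was left out, 21 of the 23 medians turned or moved by over 1.5 times, all but those of cholesterol synthesis and immediate early genes. With an estimated correlation, camera called 0 lists. Fry, which asks whether the genes of a list move at all, called 0 lists on balance and 4 in either direction. The 4 were oxidative phosphorylation (fry adjusted p = 0.0011), ribosomal proteins (0.0024), BET proteins and elongation factors (0.0024) and the proteasome (0.0077). Fry counts both mice of an array toward its degrees of freedom, although genotype varied only between arrays. Its p-values may therefore be too small, and differences between arrays in either direction could give such calls. Median, mean and test differed in sign for neuropeptides (median −0.11, mean −0.048, camera upward), for sodium and calcium channels (median −0.053, mean 0.023, camera upward), for oxidative phosphorylation (median −0.091, mean −0.0026, camera upward) and for the proteasome (median −0.046, mean 0.0050, camera downward).

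**Figure D3:**
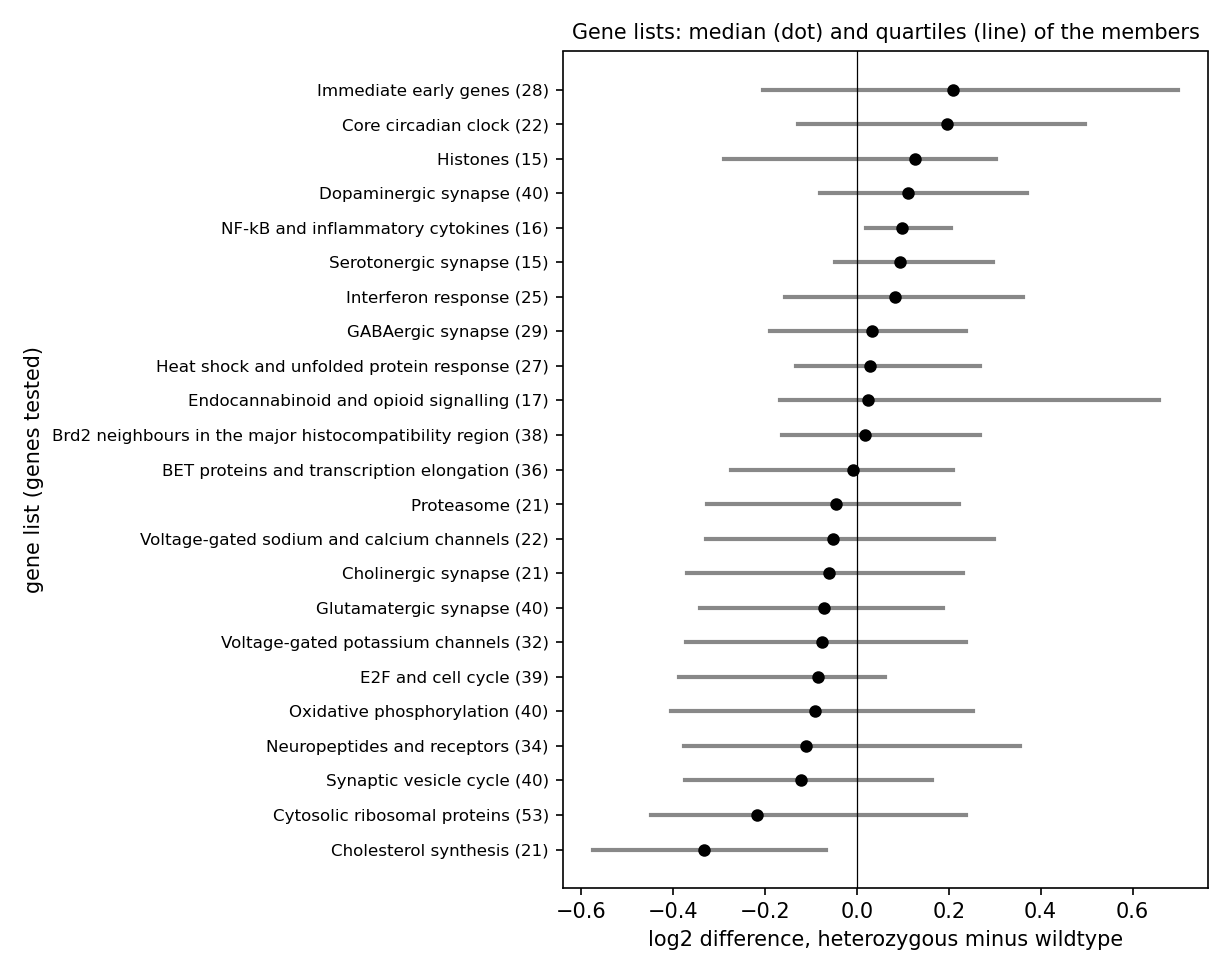
Median (dot) and quartiles (line) of the log2 differences, heterozygous minus wildtype, of the tested genes in each of 23 gene lists. Cholesterol synthesis lies lowest with a median of −0.33, immediate early genes highest with 0.21, and no list passed an adjusted p of 0.05.

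The cell type lists ask whether the dissected tissue held the same cells in both groups. Markers of cortical excitatory neurons were lower in the samples labelled heterozygous, with a median of −0.79 and 15 of 19 genes lower, and rested largely on wildtype replicate 1. Markers of striatal projection neurons had a median of 0.24 (13 of 18 higher), and rested on wildtype replicate 4, where their median stood at −0.88 against the mean of all samples. Without wildtype replicate 1 the cortical median was −0.27, and without wildtype replicate 4 the striatal median was −0.01. None of the 17 lists passed camera at an adjusted p of 0.05.

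The cortical list had an adjusted p of 0.150, and p = 0.357 with an estimated correlation. Bcl6 read 10.82 ± 0.28 in wildtype and 10.01 ± 0.03 in the samples labelled heterozygous (SD, n = 4 each). Tbr1, a transcription factor of deep cortical layers that was chosen after its values were seen, read 12.37 in wildtype replicate 1 and 8.38 to 9.69 in the other 7 samples. Striatal projection neurons, the direct pathway (median 0.32, 7 of 9 higher) and oligodendrocytes (median 0.20, 12 of 14 higher) each had an adjusted p of 0.160. With an estimated correlation these had p = 0.556, 0.230 and 0.492. Arpp19, well above background in 2 of 4 wildtype samples, stood at 1.75, Tac1 at 0.85, Ppp1r1b at 0.47 and Mobp, a myelin protein, at 0.61. The indirect pathway had a median of 0.17 (6 of 8 higher, adjusted p = 0.588), with Penk at 0.86, and the median was 0.0028 without wildtype replicate 4. Without that sample Tac1 stood at 0.57, Penk at 0.50 and Ppp1r1b at 0.15.

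Of the lists of other brain cells, interneurons had a median of 0.082 (10 of 18 higher, adjusted p = 0.822), with Chat at 1.22 and Lhx6 at −0.30 (−0.04 with the processed signals), where another Lhx6 probe read 0.75. Astrocytes had 0.050 (9 of 16 higher, adjusted p = 0.854), with Aldoc at −0.064. Oligodendrocyte precursors had −0.084 (8 of 9 lower, adjusted p = 0.514), with Lhfpl3 at −1.03 and 0.085 for its other probe. Microglia had 0.10 (11 of 18 higher, adjusted p = 0.514), with Siglech at −1.25 where the highest of its 3 probes read 0.85. Endothelial cells had 0.072 (11 of 17 higher, adjusted p = 0.588), with Cldn5, a tight junction protein, at −1.06 (SE 0.31). Mural cells had 0.022 (6 of 11 higher, adjusted p = 0.885). Among these Rgs5 stood at 1.41, Pdgfrb at 0.88 and Tagln at −2.09, with Tagln at 15.10 and 14.92 on 1 wildtype array and 12.66 and 12.48 on the other. The signs of the astrocyte and mural medians turned under another scaling, and these, the interneuron median and Aldoc (0.0098 without wildtype replicate 1) turned without 1 sample or another (interneurons −0.060, astrocytes −0.066, mural cells −0.0065).

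Of the lists of neighbouring structures, the choroid plexus had a median of −0.15 (13 of 19 lower, adjusted p = 0.780), which went from −0.56 without heterozygous replicate 3 to 0.16 without heterozygous replicate 4. Ttr, the transthyretin of the choroid plexus, spanned 6.63 to 17.36 in the wildtype samples and 12.18 to 17.21 in those labelled heterozygous. Ependymal cells had −0.39 (11 of 13 lower, adjusted p = 0.588), with Foxj1 at −0.65 (−0.99 without wildtype replicate 1, −0.40 without wildtype replicate 2), and the median was −0.0086 without wildtype replicate 2. Blood had −0.32 (6 of 8 lower, adjusted p = 0.874), with Hba-a1, an alpha globin, at 17.20 in wildtype replicate 4 and 14.39 to 16.53 in the other 7 samples. Without wildtype replicate 4 the blood median was 0.19. The sign of Hba-a1, 0.33, turned under another scaling and without wildtype replicate 3 (−0.39), and it stood at 1.09 without wildtype replicate 4. Thalamus, septum and hypothalamus had −0.034 (8 of 13 lower, mean −0.092, camera upward, adjusted p = 0.963), with Zic1 at −1.02 (−0.58 without wildtype replicate 4). Prkcd, a thalamic marker, spanned 9.16 to 14.20 in wildtype samples and 8.87 to 14.35 in those labelled heterozygous. The thalamic median was 0.097 without heterozygous replicate 2. Meningeal fibroblasts had 0.0088 (6 of 11 higher, adjusted p = 0.854), a sign that turned under another scaling and without wildtype replicate 3 (−0.11), and atrial heart muscle −0.18 (8 of 12 lower, adjusted p = 0.854), with Myl4 at −1.47. Myl4 read 11.95 in wildtype replicate 1 and 9.33 to 9.47 in the other 3 wildtype samples, and stood at −0.89 without it. When 1 sample was left out, all 17 medians of the cell type lists turned or moved by over 1.5 times. Adjusted over the list alone, 3 members passed, all mural, against 0 over all genes tested. Camera with an estimated correlation called 0 lists, and fry called 0 on balance and 2 in either direction. The 2 were mural cells (fry adjusted p = 0.0032) and endothelial cells (0.033), p-values that may be too small since both mice of an array count toward the degrees of freedom. The mural list had a mean of −0.088 against its positive median.

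**Figure D4:**
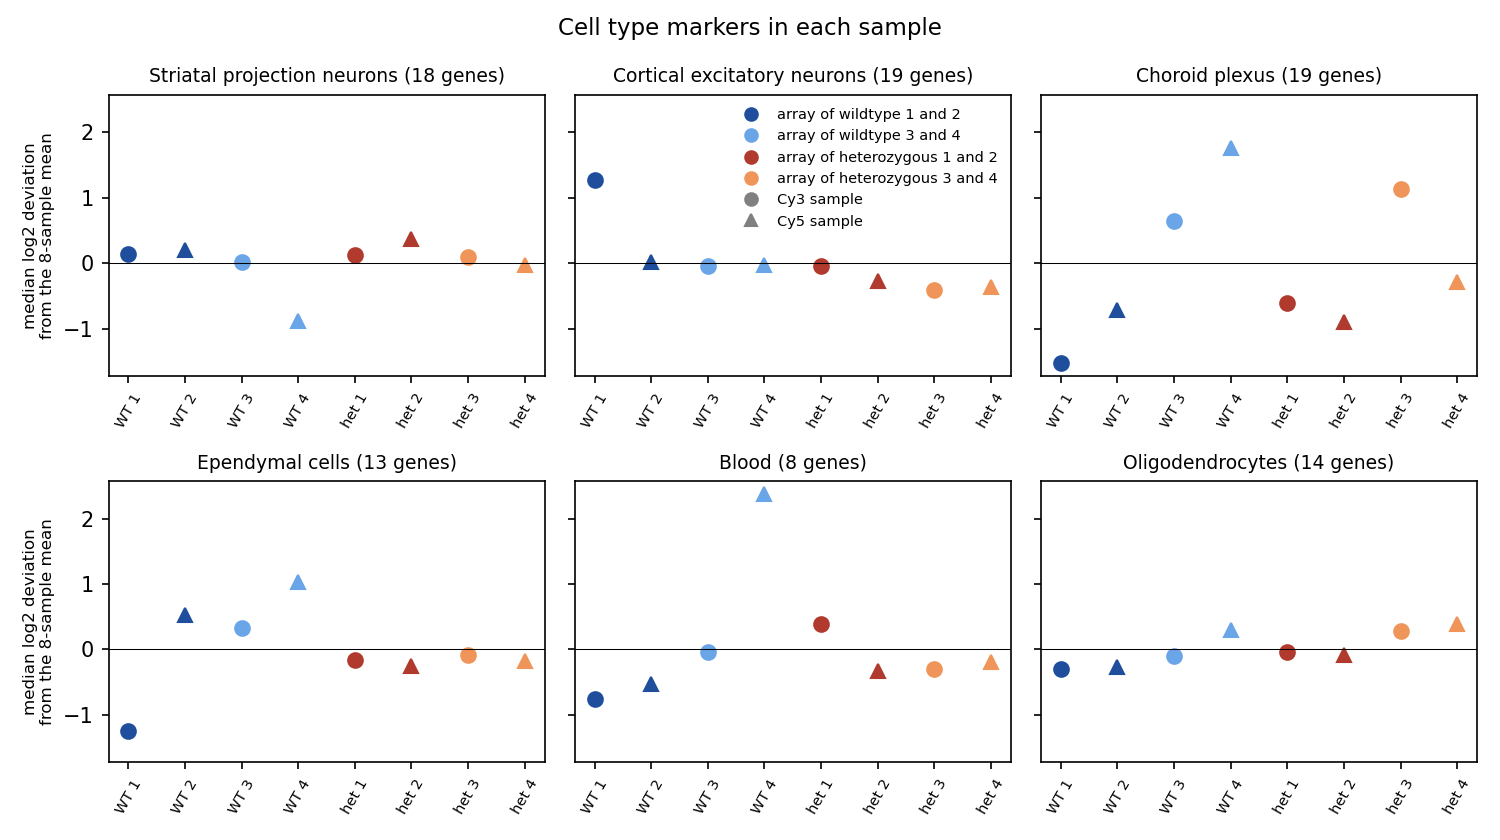
Median log2 deviation of cell type markers from the mean of all 8 samples, 1 panel per list and 1 point per sample, with colours for arrays and symbols for dyes. The cortical list stands at 1.26 in wildtype replicate 1, and the blood list at 2.37 and the choroid plexus list at 1.76 in wildtype replicate 4.

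A backcross keeps donor sequence longest around the targeted gene, so the genes within 5 Mb of Brd2 on chromosome 17 were compared with all others. The neighbourhood held no more genes at an unadjusted p under 0.05 than the rest of the genome. Of 192 tested genes near Brd2, 15 (7.81%) reached it, against 1163 of 14826 elsewhere (7.84%, two-sided Fisher's exact test across genes, p = 1). Rpp21 and Col11a2 were among the genes near Brd2, at 1.74 (0.076 for the other probe of Rpp21) and 0.95. Without the array of heterozygous replicates 3 and 4, the share was 12.9% near Brd2 against 8.79% elsewhere (Fisher's exact test across genes, p = 0.0461, the lowest of all alternatives).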

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

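The tests of replicate spots, of contrasts within arrays, of held-out markers, of the Brd2 intervals, of splits that keep arrays whole and of splits at unadjusted p alone were chosen after the results were seen. The other counts over all splits of the samples were planned.

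A sample stood far from the other 3 of its group in 15 of 244 groups looked at (6.15%). The cutoff gives about 1 in 20 groups for independent samples. The 2 mice of an array were not independent, and the genes were picked with their values in view. The share can therefore not be set against chance. The number that follows each is the sample's gap to its nearest neighbour as a share of the group's range. Among lists, these were BET proteins in wildtype replicate 4 (0.954), cholesterol synthesis in heterozygous replicate 3 (0.830), the indirect pathway in heterozygous replicate 1 (0.8405), cortical excitatory neurons in wildtype replicate 1 (0.954), thalamus, septum and hypothalamus in heterozygous replicate 4 (0.865), meningeal fibroblasts in heterozygous replicate 2 (0.840) and atrial heart muscle in heterozygous replicate 3 (0.854). Among genes, these were Lyrm2 (0.870), Tbr1 (0.848) and Myl4 (0.947) in wildtype replicate 1, Aff4 in wildtype replicate 3 (0.881), Rpl29 (0.839), Hba-a1 (0.880) and Aldoc (0.849) in wildtype replicate 4, and Siglech in heterozygous replicate 4 (0.886).

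The groups lay apart in 16.9% of genes while none passed the adjusted test. Probes with 10 spots on an array show how much the place on the array adds, since replicate spots of 1 probe deviated together in both dyes (median correlation 0.968). Genes read by such probes had no overlap of the groups less often than the others, 8.79% of 239 genes against 17.1% of 14779 (Fisher's exact test across genes, p = 0.000344). Spot differences between arrays, shared by both dyes, are therefore a candidate explanation for part of the separation. A difference between the genotypes remains open and cannot be separated from the arrays that carry them. An unadjusted p under 0.05 was reached by 0% against 7.97%. These 2 shares decide nothing, since the moderated test draws each gene's variance toward that of all genes, most of which are read by 1 spot. Of 35 splits of the samples into 4 and 4, 34 could be fitted. At an unadjusted p under 0.05 and at least 1.5-fold, the real split had the most genes (1 of 34 splits as large, real 1090, highest other 836, each with the array correlation from 2000 genes). This decides nothing about chance, since every split that keeps arrays whole (571 to 1090 genes) lay above every split that breaks them (29 to 563), and the splits that keep arrays whole are 3 (1 of them as large, real 1090, highest other 836), too few for a share under 0.05. At an unadjusted p under 0.05 with no limit on the fold, 12 of 34 splits gave as many genes (real 1134, highest other 1592), but the 11 others all break arrays and are fitted with the precision within arrays, so this decides nothing either. Of the 3 splits that keep arrays whole, 1 was as large (real 1134, highest other 865), again too few.

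The counts of genes, gene lists and cell type lists past the adjusted threshold were 0 in the real split, so that all 34 of 34 splits give as many and the splits decide nothing about chance. The highest of the other splits was 89 genes, 12 gene lists and 10 cell type lists. Of the 33 other splits, 3 had a gene past the threshold, 29 a gene list and 32 a cell type list. The 2 other splits that keep arrays whole gave 0 genes, 0 gene lists, and 2 and 0 cell type lists. The rest break arrays and are fitted with the precision within arrays. Such counts therefore do not by themselves point to a structure of the samples.

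Mice of the same genotype differed in markers of neighbouring structures. Of 68 contrasts between the mice of 1 array, 14 lay outside the range of 10000 random lists, so spot differences shared by both dyes do not account for them. Every other member of the cortical, choroid plexus, ependymal and blood lists was used to choose the sample where the list stood highest, and of the members held out, 88.9% (cortical, wildtype replicate 1) to 100% (the others, wildtype replicate 4) lay above the array partner. The markers of a list thus moved together, and neighbouring tissue in some dissections may contribute. Each such contrast also sets Cy5 against Cy3. The choroid plexus and blood lists lay outside the random range in both directions, whereas the list of thalamus, septum and hypothalamus was higher in the Cy5 sample on all 4 arrays (0.17 to 0.59, 3 of the 14), where dye and mouse are not separated. No biological explanation was tested, since no label sets these mice apart.

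Brd2 was not lower in the samples labelled heterozygous. Spread between arrays could hide a loss of 1 of the 2 alleles, since the 95% interval with the spatial trend removed reached −1.14, below the −1 that such a loss would give, although the planned fit's interval ended at −0.52. The dimmer probe goes against such a loss in the sequence it reads, with an interval of 0.24 to 1.53 in the planned fit and −0.10 to 0.82 with the spatial trend removed. All of these intervals count both mice of an array toward their degrees of freedom. Genotype varied only between the 4 arrays, so the intervals may be too narrow. The place of the probes against the trap is not given in the labels, and a sample with another genotype than its label was not tested. These explanations cannot be told apart here, for want of a probe placed against the trap.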

How the results depend on the processing

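The alternatives with the spatial trend removed, with outlier spots kept and without wildtype replicates 1 and 4 were chosen after the results were seen. All other alternatives were planned. The 0 genes past an adjusted p of 0.05 became 1 with the deposited table, 443 with no array block, 17 without the array of wildtype replicates 1 and 2, 12 without that of 3 and 4, 7 without that of heterozygous replicates 3 and 4, 1 with the spatial trend removed and 1 without wildtype replicates 1 and 4. Leaving out 1 sample gave 0 to 1, the 1 being Olfr1349 without wildtype replicate 4. The 1121 genes at unadjusted p under 0.05 and at least 1.5-fold became 602 with processed signals, 1831 with no array block, 2450 without the array of wildtype replicates 1 and 2 and 265 with the spatial trend removed, and 865 to 1057 without 1 sample. With no array block the mice of an array count as independent. The other causes were not tested.

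The 0 gene lists past the threshold became 1 with no dim-probe filter, with the filter in all 8 samples, with the mean of probes, with no array block, with channels averaged, in Cy3 samples and with outlier spots kept, 2 without the array of wildtype replicates 3 and 4 and with the spatial trend removed, and 4 in Cy5 samples. Without 1 sample it was 0 to 2 (2 without heterozygous replicate 1, 1 without wildtype replicate 2 or 3). The 0 cell type lists became 1 with the deposited table, no array block, channels averaged and outlier spots kept, 2 in Cy3 samples, without the array of wildtype replicates 3 and 4, without that of heterozygous replicates 1 and 2, with the spatial trend removed and without wildtype replicates 1 and 4, 3 without the array of wildtype replicates 1 and 2, and 6 in Cy5 samples. Without 1 sample it was 0 to 3 (3 without wildtype replicate 3, 2 without wildtype replicate 2 or heterozygous replicate 2, 1 without wildtype replicate 1 or 4 or heterozygous replicate 4). The cause was not tested.

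Brd2 reversed to −0.042 with processed signals, −0.27 without the array of wildtype replicates 1 and 2 and −0.40 with the spatial trend removed. The share of genes within 5 Mb of Brd2, 7.81% and below the share elsewhere, lay above the share elsewhere at 5.21% with processed signals, 7.81% with quantile normalization, 6.81% with the deposited table, 8.33% with offset 16, 9.24% with no dim-probe filter, 23.4% with no array block, 6.25% with channels averaged, 7.53% in Cy3 samples, 6.60% in Cy5 samples, 10% without the array of heterozygous replicates 1 and 2, 12.9% without that of 3 and 4, 8.33% with trend and robust, 4.17% with the spatial trend removed, 9.13% with outlier spots kept, 10.9% without wildtype replicates 1 and 4 and 6.74% to 9.42% without 1 sample. The cause was not tested. The replicate numbers share only the dye: deviations of same-numbered samples correlated at 0.04, 0.25, 0.16 and 0.13 across genes, and 2 of the 4 pairs correlated best with their own number. With the replicate block in place of dye, 0 genes, 1 gene list and 1 cell type list passed, and the share near Brd2 was 11.5%. The shares near Brd2 moved together with the count over all 15018 genes at an unadjusted p under 0.05. That count was 1178 in the planned fit, 1689 with the replicate block, 3150 with no array block and 495 with the spatial trend removed. Fisher's exact test across genes gave a p of at least 0.0461 in each of the 30 alternatives where it was run. Of 1240 list medians under the alternatives, 1067 kept their sign and side, 119 changed sign with no call and 54 passed. Of 2495 values of single genes, 2408 kept both, 39 changed sign with no call and 48 passed. Each gene is read by its brightest probe without an outlier spot, so that another probe reads it in some alternatives. Leaving out 1 sample brought in another probe for Impdh2 (0.84), Scn3a (0.26), Nmb (0.62) and Sdhb (0.076), and keeping outlier spots did so for Impdh2, Scn3a and Sdhb again, for Rplp0 (−0.75), Atp5k (−0.16), Hspe1 (0.15), Mgll (0.23) and Slc32a1 (0.47), and for Pdyn, Rpl29 and Mobp, which moved by less than 1.5 times. Over both, 43 of the passes came with no array block. The median signal over background, 3.72 to 10.6, limits what dim probes show.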

Other observations

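The values here were chosen after the results were seen, and none is a test of genotype. Mice that shared an array, and so a genotype, differed in whole sets of markers, and each such pair also sets Cy5 against Cy3. In wildtype replicate 4, all 18 tested markers of striatal projection neurons lay below its array partner, wildtype replicate 3 (median −0.90), while 14 of 14 oligodendrocyte markers (median 0.39), 19 of 19 choroid plexus markers (1.01), 13 of 13 ependymal markers (0.71) and 8 of 8 blood markers (2.56) lay above it. Among the genes of these sets, Ttr read 17.36 in wildtype replicate 4 and 15.26 in replicate 3, and Hba-a1 read 17.20 and 14.39. In wildtype replicate 1, 16 of 19 cortical markers lay above wildtype replicate 2, with Tbr1 at 12.37 against 8.90, while 13 of 13 ependymal markers lay below it, with Foxj1 at 8.37 against 9.73. In heterozygous replicate 3, 18 of 19 choroid plexus markers lay above heterozygous replicate 4, with Ttr at 17.21 against 14.65. The list of thalamus, septum and hypothalamus was higher in the Cy5 sample on all 4 arrays (medians 0.17 to 0.59). In heterozygous replicate 1, 7 of 8 blood markers lay above heterozygous replicate 2.

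Replicate spots gave the spread within an array. Over the probes with 10 spots, the mean of both channels had a median SD between spots of 0.28 to 0.47 log2 units on the 4 arrays, and the ratio of the channels 0.07 to 0.14. The median SD between arrays was 0.176 for genes read by 10 spots and 0.328 for genes read by 1 spot.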
